A study of Homo sapiens with 8 samples.

How the data were processed

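RNA of VCaP cells was sequenced in 8 libraries. VCaP is a human prostate cancer cell line that carries the TMPRSS2-ERG fusion, per the labels. Cells were transfected with small interfering RNA (siRNA) for 72 hours, with either a non-targeting control, an siRNA against APC or an siRNA against RNF43, and part of the RNF43 cultures received recombinant Wnt3a at 100 ng/ml near the end of that time. Total RNA was extracted with a silica column kit and libraries were prepared with a directional (strand-keeping) kit, per the labels' protocols.

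Each library came with a deposited table of counts, the number of reads that the authors assigned to each Ensembl gene identifier, with no normalization. The submitters' processing notes name HISAT2, SAMtools, HTSeq and the hg38 genome, without versions. The annotation release and the strand setting of the counting are not given in the sources used here, so reads of overlapping or antisense genes, and of near-identical paralogs or pseudogenes, may not be fully separated in these counts. Each table held 44285 gene identifiers and 5 summary lines that name no gene. These lines were kept out of library sizes and tests. Reads with more than 1 alignment made up 34.2% of the reads listed for control replicate 2 and 21.1% to 26.1% in the other libraries. Reads in no annotated feature made up 5.33% to 6.11% and ambiguous reads 1.54% to 1.76%. The summary lines of control replicate 2 were written in another style than those of the other 7 tables. Gene symbols came from a table of gene names for 30621 identifiers and from GENCODE release 29 for another 4466, and 9198 identifiers with 1.45% of the counts had no symbol. Positions are from GENCODE release 29 on GRCh38, which 15374 of the 16295 tested genes matched.

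Libraries were grouped by their titles into a control, APC knockdown, RNF43 knockdown and RNF43 knockdown with Wnt3a, with 2 libraries in each. The APC libraries came from siRNAs numbered 2 and 4 in the titles, whereas the protocol text numbers the second of them 3. Each RNF43 group held siRNA 3 and siRNA 4. The treatment tags of a pair of RNF43 libraries contradict their titles about Wnt3a. The titles were used because the design text puts both RNF43 siRNAs under both conditions, and the tags were tried as an alternative. The titles give 7 and 6 hours of Wnt3a, and the protocol text gives 7. The labels call the samples biological duplicates without saying what was kept separate, so p-values measure the spread between these libraries, which may be partly technical, and within each knockdown group it includes any difference between siRNAs.

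Total gene counts ran from 22029698 to 35201605 per library. Genes were kept with edgeR's filterByExpr, which left 16295. Counts were normalized with TMM factors and tested with edgeR's quasi-likelihood F test (version 4.0.16 in R 4.3.3, robust fits, two-sided) in a single model of 4 groups over all 8 libraries, with 4 residual degrees of freedom and Benjamini-Hochberg adjustment at 0.05. The comparisons were APC knockdown against control, Wnt3a against no Wnt3a within RNF43 knockdown, RNF43 knockdown against control, the difference between the APC and Wnt3a changes, and the difference of the Wnt3a change between the RNF43 siRNAs. The last has 1 library per cell of the design and 2 residual degrees of freedom, and its lone libraries were assumed to vary like the control and APC pairs. Values per library are CPM, counts relative to the TMM-scaled library size, and log2 fold changes carry the standard error (SE) of the fit. Intervals are 95% intervals. For a gene with 0 counts in all libraries of a group, the fold is a lower bound against 3 counts over that group. For a gene with 1 to 3 counts in a group, the ratio of counts carries an exact binomial interval. Such intervals and bounds cover counting error only.

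Gene lists were fixed before the data were examined: Wnt/beta-catenin targets and feedback genes, Wnt ligands, Wnt receptors, secreted Wnt antagonists, the intracellular pathway core, noncanonical and planar cell polarity components, androgen-induced genes, neuroendocrine markers, mesenchymal markers, luminal epithelial markers, proliferation genes, interferon-stimulated genes, p53 targets, stress genes, cholesterol synthesis genes, TGF-beta and BMP targets, markers of other cell types, mitochondrially encoded mRNAs, and histone and nuclear RNAs. Of these 19 lists, 18 with at least 5 tested members were tested with camera (limma 3.58.1, preset correlation of 0.01), with adjustment over the lists of a comparison. No mitochondrially encoded mRNA was tested, since the deposited counts assign 0% of reads to them. Named genes followed a rule fixed at the same time. It takes APC, RNF43, ROR1, ROR2, WNT5A and AXIN2 always, then per comparison the 10 rising and 10 falling genes with the largest log2 fold change that passed, had at least 1 CPM in the higher group and had both libraries of a group beyond both of the other, or the 5 of smallest p where fewer than 3 qualified in a direction, then the 4 members of smallest p of each list.

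The siRNA number was also fitted as a replicate block over the RNF43 libraries, with 3 residual degrees of freedom. It was treated as pairing because libraries with the same number received the same siRNA. In a check of this, the difference between siRNA 3 and siRNA 4 correlated at 0.697 across genes between the libraries without and with Wnt3a. Other alternatives were DESeq2 (1.42.0), limma-voom, RLE size factors, no count filter or a mean of at least 1 CPM, only the 4 libraries compared, each library left out, an estimated correlation or fry for the lists, and grouping by the treatment tag. In 3 simulated data sets per comparison, each with 200 of 16295 genes changed, the test recovered 55.3% of 4-fold and 86% of 8-fold changes in the Wnt3a comparison, 54.7% and 78% in the APC comparison, and 56% and 84% in the RNF43 comparison, but 0% to 2% of 2-fold changes. The changed genes were drawn from those with a mean of at least 1 CPM, and a list of 30 more such genes was raised 2-fold. Both control libraries were drawn from the same mean per gene, so a difference shared across genes, as between the real controls, was not simulated. Overlap of the APC and RNF43 comparisons was set against 40 simulations of unchanged groups, since both used the same controls. No group held enough libraries for a test of outlying samples or for other splits of the samples.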

Results

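The series measured gene expression in VCaP cells after siRNA knockdown of APC, the scaffold of the complex that marks beta-catenin for degradation, or of RNF43, a ubiquitin ligase that removes Wnt receptors from the cell surface. Its design text names 2 comparisons, APC knockdown against control and Wnt3a stimulation within RNF43 knockdown, and the series title points to the Wnt receptor ROR1. Loss of APC and added Wnt3a can each turn on canonical Wnt signalling, by different routes, so the comparisons ask which genes respond to it. Each of the 4 groups had 2 libraries. The control libraries held 28644267 and 30332153 gene counts, APC knockdown 27438538 and 26130532, RNF43 knockdown 23102165 and 27405446, and RNF43 knockdown with Wnt3a 22029698 and 35201605. All error terms on log2 fold changes below are SE with 2 libraries per group.

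The targeted genes were lower in the libraries named for them. APC (chromosome 5, 112707498 to 112846239) had 30.2 and 29.96 CPM in the controls and 6.20 and 5.54 CPM after APC siRNA, and fell by 2.36 ± 0.21 on the log2 scale (edgeR adjusted p = 0.00291). Its level was 29.9 and 27.2 CPM after RNF43 siRNA. RNF43 (chromosome 17, 58352500 to 58417595) had 36.8 and 52.9 CPM in the controls and 6.86 and 7.32 CPM after RNF43 siRNA. As a target named in advance, it had an unadjusted edgeR p of 3.26e-06 (fold 0.16, interval 0.1 to 0.25). Across all genes its log2 fold change of -2.66 ± 0.23 missed the threshold (edgeR adjusted p = 0.0531). It passed with DESeq2 (log2 -2.64, adjusted p = 1.77e-17), and in edgeR without control replicate 1 (log2 -2.89, adjusted p = 0.0173) or without control replicate 2 (log2 -2.37, adjusted p = 0.0357). In edgeR it did not pass without RNF43 siRNA 3 (log2 -2.61, adjusted p = 0.924), without RNF43 siRNA 4 (-2.7, 0.823), with the replicate block (-2.66, 0.0938) or with RLE factors (-2.64, 0.0572). In the cultures with RNF43 siRNA and Wnt3a, RNF43 stood at 12.1 and 14.2 CPM.

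**Figure D1:**
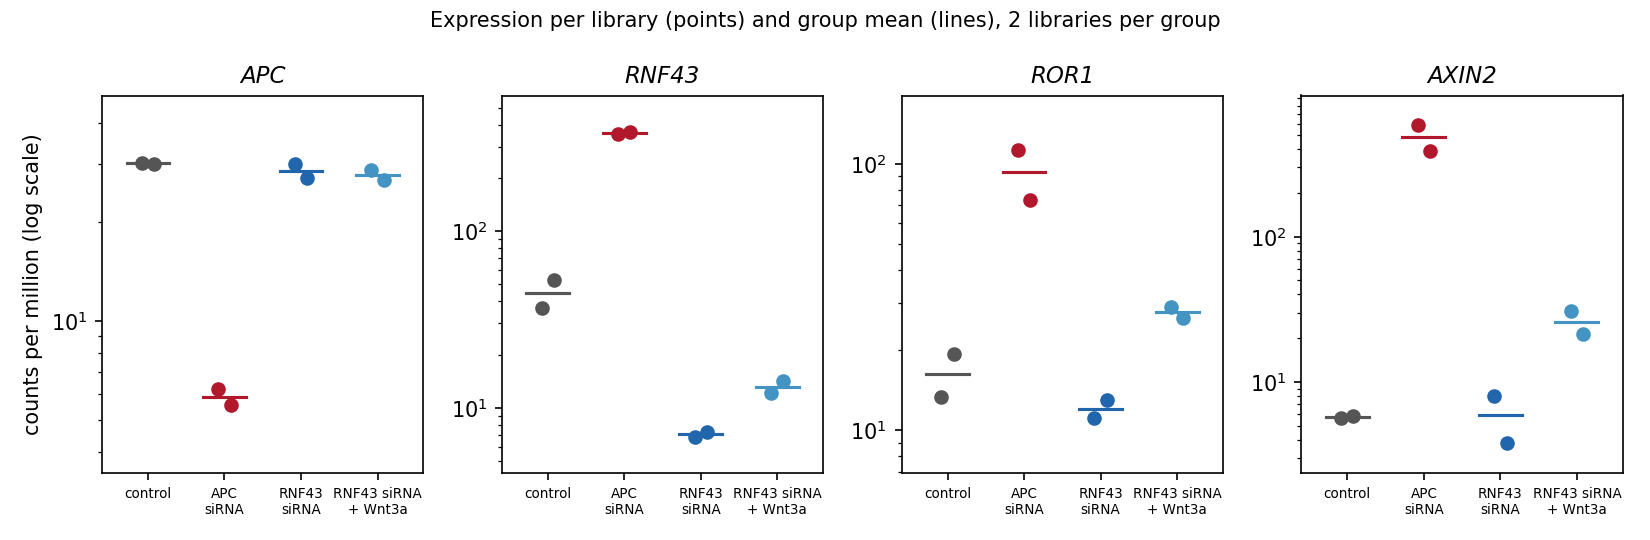
CPM on a log axis for APC, RNF43, ROR1 and AXIN2 in the 4 groups, with a point for each of the 2 libraries and a line at the group mean. APC is low only in the APC siRNA libraries (6.20 and 5.54 CPM), RNF43 is lowest in the RNF43 siRNA libraries (6.86 and 7.32 CPM) and highest after APC siRNA (352 and 366 CPM), and AXIN2 is at 587 and 391 CPM after APC siRNA and at 30.8 and 21.3 CPM with Wnt3a.

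APC knockdown raised AXIN2, RNF43 and ZNRF3, which encode negative regulators of the Wnt pathway. AXIN2 (chromosome 17, 65528563 to 65561647), a scaffold of the beta-catenin destruction complex, rose from 5.73 ± 0.125 to 489 ± 139 CPM (SD, n = 2), a log2 fold change of 6.41 ± 0.46 (edgeR adjusted p = 0.00123). RNF43 itself rose 8-fold, from 44.9 ± 11.3 to 359 ± 9.31 CPM (SD, n = 2; log2 3.00 ± 0.23, edgeR adjusted p = 0.0014), and its homologue ZNRF3 rose by 3.49 ± 0.26. ROR1 (chromosome 1, 63774022 to 64181498), a receptor for noncanonical Wnt ligands, had 13.4 and 19.3 CPM in the controls and 113 and 73.0 CPM after APC siRNA, and rose by 2.51 ± 0.30 (edgeR adjusted p = 0.00689). Its relative ROR2 (0.693 and 0.265 CPM on average in control and APC knockdown) and the ligand WNT5A (3.67 and 3.81 CPM) did not pass, with edgeR adjusted p of 0.578 and 0.983.

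Of the 16295 genes tested, 379 were higher and 73 lower after APC knockdown (edgeR, adjusted p under 0.05). Among the 10 largest rises were the secreted cysteine protease inhibitors CST1 (log2 14.36 ± 1.43) and CST4 (10.12 ± 1.24), and DACT1, a Dishevelled-binding regulator of Wnt signalling (10.90 ± 1.88). CST1 went from 0.15 to 3221 CPM on average. Reads of these closely related cystatin genes may not be fully separated. Several of the genes had 0 counts in both controls, so only lower bounds can be given. TMEM252 was at least 241-fold higher, the Norrin gene NDP at least 122-fold, TTC29 at least 110-fold, LRRC55 at least 86.6-fold, the immune checkpoint receptor gene CTLA4 at least 77.5-fold and the transcription factor gene ASCL4 at least 71-fold. The phosphatase gene PTPRO had 1 control count, a count ratio of 1270 (interval 227 to 50200). The 10 largest falls, besides APC, were in GRIA2, a glutamate receptor subunit (log2 -3.55 ± 0.42), the chemokine receptor ACKR3 (-3.54 ± 0.69), alpha-fetoprotein AFP (-3.10 ± 0.49), CRTAM (-2.79 ± 0.45), ERP27 (-2.76 ± 0.46), the Rac exchange factor PREX1 (-2.75 ± 0.44), thrombospondin THBS1 (-2.63 ± 0.51), TPSG1 (-2.45 ± 0.49) and BLNK (-2.37 ± 0.45). THBS1 had 663 and 1750 CPM in the controls and 195 and 194 CPM after APC siRNA.

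The list of Wnt/beta-catenin targets and feedback genes rose as a group. Of its 33 tested members, 18 rose and none fell over all genes tested, and 24 rose when adjusted over the list alone (camera adjusted p = 1.63e-49 with the preset correlation, adjusted p = 0.0532 with an estimated correlation). The nuclear transcription factor SP5 rose by 7.24 ± 0.40, the Dishevelled inhibitor NKD1 by 7.10 ± 0.34 and the stem cell receptor LGR5 by 7.36 ± 0.94. Other members did not pass, among them MYC (log2 -0.39 ± 0.50), CCND1 (-0.17 ± 0.26) and SOX9 (-0.63 ± 0.33), which were named after their values were seen. Of 10 secreted Wnt antagonists, NOTUM (5.43 ± 0.53), WIF1 (6.44 ± 0.76), DKK4 (a count ratio of 80.1 over 3 control counts, interval 27 to 392) and DKK3 (7.76 ± 1.39) rose, and 5 rose adjusted over the list alone (camera adjusted p = 7.66e-07, adjusted p = 0.469 with an estimated correlation). NOTUM, WIF1, DKK4 and DKK1 are also members of the Wnt target list, so these list results are not separate. Among 19 Wnt receptors, ROR1 and LGR5 rose while LGR4 (-1.59 ± 0.19) and the Frizzled gene FZD4 (-1.95 ± 0.30) fell, and adjusted over the list alone 4 rose and 2 fell (camera adjusted p = 0.608). The ligands WNT11 (6.51 ± 1.15) and WNT5B (4.64 ± 0.97, edgeR adjusted p = 0.0499) were the 2 of 14 that rose, in either adjustment (camera adjusted p = 0.608). They, ROR1 and the polarity gene VANGL2 (2.60 ± 0.37) were the 4 of 32 noncanonical and polarity genes that rose, with 5 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.433). In the pathway core, APC alone of 26 members passed, in either adjustment, and CTNNB1, which encodes beta-catenin, had a log2 fold change of 0.67 ± 0.20 (edgeR adjusted p = 0.142; list, camera adjusted p = 0.684).

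The cholesterol synthesis list also stood higher after APC knockdown (camera adjusted p = 8.56e-11, adjusted p = 0.626 with an estimated correlation). NSDHL (1.66 ± 0.27, edgeR adjusted p = 0.0206) was the 1 of 24 members that rose over all genes tested, and 16 rose adjusted over the list alone. SQLE had a log2 fold change of 1.0 ± 0.22 (edgeR adjusted p = 0.0563, and 0.0451 with the replicate block). The list was also lower in control replicate 2 than in control replicate 1, by a median of -0.67 on the log2 scale. Its median after APC knockdown was 0.78 against control replicate 1 and 1.34 against control replicate 2. The list also stood higher after RNF43 knockdown against the same controls (camera adjusted p = 5.67e-10, adjusted p = 0.641 with an estimated correlation). The rise was thus not particular to APC knockdown. Of 31 androgen-induced genes, the ion channel gene TRPM8 fell (-1.61 ± 0.20), in either adjustment (list, camera adjusted p = 0.214). The neuronal RNA-binding protein gene ELAVL4 (2.95 ± 0.57) rose among 15 neuroendocrine markers, with 2 higher adjusted over the list alone, and NCAM1 had a log2 fold change of 3.44 ± 0.76 (edgeR adjusted p = 0.0579, and 0.0446 with the replicate block; list, camera adjusted p = 0.547). Of 9 mesenchymal markers MMP2 rose (4.45 ± 0.71), with 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.547). Markers of other cell types went both ways in these line cells, with CSF1R at least 37.6-fold higher and DCN lower (a count ratio of 12.3 over 2 counts, interval 3.1 to 106), also adjusted over the list alone (camera adjusted p = 0.94). With edgeR, no member passed in either adjustment among 16 epithelial, 28 proliferation, 20 interferon-stimulated, 20 p53, 24 stress, 17 TGF-beta and BMP, and 8 histone and nuclear RNA genes, whose camera adjusted p were 0.243, 0.338, 0.608, 0.853, 0.813, 0.0561 and 0.214. DESeq2 called members of these lists lower over all genes, among them OCLN (log2 -0.99, adjusted p = 0.0232), MCM6 (-0.83, 0.00945), BTG2 (-1.19, 0.0285), FAS (-1.47, 0.0324), BMP2 (-3.45, 0.0294), HEY1 (-2.25, 0.0202) and ID2 (-1.88, 0.0136), and edgeR with the replicate block called MCM6 (-0.84, adjusted p = 0.0492). Proliferation genes were higher in control replicate 2 than in control replicate 1 by a median of 1.67 on the log2 scale, and TGF-beta and BMP targets by 1.6. Without control replicate 1, camera called the proliferation list lower (adjusted p = 6.78e-14), the TGF-beta and BMP list lower (1.44e-06) and the histone and nuclear RNA list lower (0.0148). Without control replicate 2, it called the proliferation list higher (adjusted p = 6.29e-07) and the androgen-induced list lower (0.000624).

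The counts of changed genes depended on single libraries. Without control replicate 1 the test called 450 higher and 404 lower, without control replicate 2 189 and 34, without APC siRNA 2 57 and 1, and without APC siRNA 4 185 and 5, and with the replicate block it called 597 and 193. The calls for AXIN2, RNF43, ZNRF3, NKD1, SP5, CST1, NDP, NOTUM, WIF1 and APC stood whichever library was left out. ROR1 (edgeR adjusted p = 0.0596) lost its call without APC siRNA 2, and LGR5 lost it without APC siRNA 2 (0.0596) and without control replicate 2 (0.0567). The falls named above other than APC lost their calls without APC siRNA 2, with edgeR adjusted p from 0.0808 for GRIA2 to 0.409 for TPSG1, and without APC siRNA 4, from 0.0582 for GRIA2 to 0.244 for TPSG1. Without control replicate 2 the calls of ACKR3 (0.0705), CRTAM (0.0665), ERP27 (0.069), THBS1 (0.121), TPSG1 and BLNK were lost as well. Among the rises, DACT1 lost its call without control replicate 1 (0.0796), control replicate 2 (0.15) or APC siRNA 2 (0.11), and WNT11 likewise (0.0758, 0.145 and 0.177). TMEM252 lost its call without the same libraries (0.0626, 0.118 and 0.0977), and WNT5B and DKK3 without any of the 4. Other named genes lost their calls without APC siRNA 2, namely TTC29 (0.0595), CST4 (0.0622), PTPRO (0.0502), LRRC55 (0.104), CTLA4 (0.106), ASCL4 (0.14), LGR4 (0.0926), FZD4 (0.192), DKK4 (0.0952), VANGL2 (0.133), TRPM8 (0.106), NSDHL (0.0972), ELAVL4 (0.256), MMP2 (0.177), CSF1R (0.0808) and DCN (0.324). Without APC siRNA 4 this held for CTLA4 (0.0647), ASCL4 (0.0598), LGR4 (0.0647), FZD4 (0.0925), TRPM8 (0.0695), NSDHL (0.13), ELAVL4 (0.17), CSF1R (0.0603) and DCN (0.232). Without control replicate 2 it held for CST4 (0.0521), PTPRO (0.08), LRRC55 (0.0567), ASCL4 (0.0686), VANGL2 (0.0539), NSDHL (0.0781), ELAVL4 (0.0511), MMP2 (0.0719) and DCN (0.0733), and without control replicate 1 for ELAVL4 (0.06), MMP2 (0.0545) and DCN (0.0557). With DESeq2, TMEM252 (adjusted p = 0.195), ASCL4 (0.345) and DCN (0.114) did not pass.

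In the Wnt3a comparison within RNF43 knockdown no gene passed the edgeR test over all genes. Libraries were grouped by their titles, which the treatment tags of a pair of them contradict. The largest in significance was ETS2, an ETS-family transcription factor gene, with 16.0 and 14.1 CPM without Wnt3a and 139 and 91.3 CPM with it (log2 2.93 ± 0.25, edgeR adjusted p = 0.051). TBC1D4, a regulator of glucose transporter traffic, had a log2 fold change of 2.26 ± 0.22 (edgeR adjusted p = 0.0615), the transcription factor gene RUNX1 of 3.96 ± 0.53 (0.238) and CABP7 of 4.55 ± 0.61 (0.238). AXIN2 had 8.03 and 3.79 CPM without and 30.8 and 21.3 CPM with Wnt3a (log2 2.14 ± 0.38, edgeR adjusted p = 0.876). ROR1 had 11.1 and 13.0 CPM without and 29.1 and 26.4 CPM with Wnt3a (log2 1.2 ± 0.29, edgeR adjusted p = 1). Among the genes always named, unadjusted edgeR p were 0.00311 for ROR1, 0.000537 for AXIN2 and 0.00416 for RNF43. They were 0.848 for APC, 0.554 for ROR2 and 0.918 for WNT5A. The folds of ROR1 and AXIN2 were 2.3 (interval 1.32 to 4.01) and 4.41 (2.11 to 9.23). For ROR2 and WNT5A the log2 fold changes were 0.68 ± 1.10 and 0.08 ± 0.75, and RNF43 had 0.89 ± 0.22. On the lower side, DDIT4 (-1.12 ± 0.26), DIRAS2 (-1.40 ± 0.35), FAM110B (-1.20 ± 0.31), PTGER4 (-1.22 ± 0.33) and the ribosomal pseudogene RPL7P13 (-1.63 ± 0.44) had the smallest p, each with an edgeR adjusted p of 1.

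The edgeR test called 0 genes higher and 0 lower, with 144 and 63 at an unadjusted p under 0.05. That is fewer than the 815 expected by chance, so the test appears conservative here. Its spread includes the difference between siRNAs within each group, and with the replicate block 364 genes had such a p. The 0 calls thus do not show that Wnt3a changed no gene. DESeq2 called 24 higher and 0 lower, and limma-voom 0 of either. Calls with the replicate block are less certain, as in simulated data its share of false calls exceeded the threshold. With the replicate block, edgeR called 6 genes higher, ETS2 (log2 2.91, adjusted p = 0.0259), CABP7 (4.58, 0.0259), DST (2.0, 0.0259), TBC1D4 (2.24, 0.0409), RUNX1 (3.83, 0.0409) and CDC14A (2.47, 0.0409), of which DST and CDC14A were named after their values were seen. Leaving out the library with siRNA 4 and Wnt3a gave 2 calls, ETS2 (log2 3.21, edgeR adjusted p = 0.0264) and RUNX1 (4.52, 0.0316).

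The list of Wnt targets and feedback genes was the 1 list of 18 that passed in the Wnt3a comparison, in the upward direction (camera adjusted p = 1.66e-27, adjusted p = 0.136 with an estimated correlation, adjusted p = 0.304 with that and the replicate block). Of its 33 members 0 passed over all genes tested in edgeR and 10 rose adjusted over the list alone, among them NKD1 (log2 2.65 ± 0.32), SP5 (2.43 ± 0.34), AXIN2 and TNFRSF19 (2.83 ± 0.56). DESeq2 called these 4 higher over all genes, with adjusted p of 1.08e-06 for NKD1, 4.71e-06 for SP5, 0.000183 for AXIN2 and 0.000131 for TNFRSF19, and LGR5 as well (log2 3.78, adjusted p = 0.0147). The other lists had camera adjusted p from 0.212 for androgen-induced genes to 0.932 for mesenchymal markers, and with edgeR 0 members passed in any of them in either adjustment, while LGR5, also in the receptor list, passed with DESeq2. Leaving out single libraries added list calls. Without RNF43 siRNA 3 the ligand, antagonist and other cell type lists (each adjusted p = 0.00987) and the cholesterol list (0.0338) were higher, and without RNF43 siRNA 4 the neuroendocrine and interferon lists (each 0.0178) and the histone and nuclear RNA list (0.0188) were lower. Without siRNA 3 with Wnt3a the interferon list was lower (0.0368), and without siRNA 4 with Wnt3a the antagonist (0.0127) and other cell type lists (0.0058) were higher. In the receptor list, LGR5 had a log2 fold change of 3.72 ± 1.0, FZD10 of 1.74 ± 0.63 and LGR4 of -0.45 ± 0.19, and in the androgen list TMPRSS2 had -0.58 ± 0.20, all with an edgeR adjusted p of 1. A test of whether the Wnt3a change differed between the 2 RNF43 siRNAs made 0 calls in edgeR and 0 in DESeq2, with 81 and 32 genes at an unadjusted p under 0.05. It rests on 1 library per siRNA and condition with 2 residual degrees of freedom, and its recovery was not simulated, so it does not show that the change was alike.

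**Figure D2:**
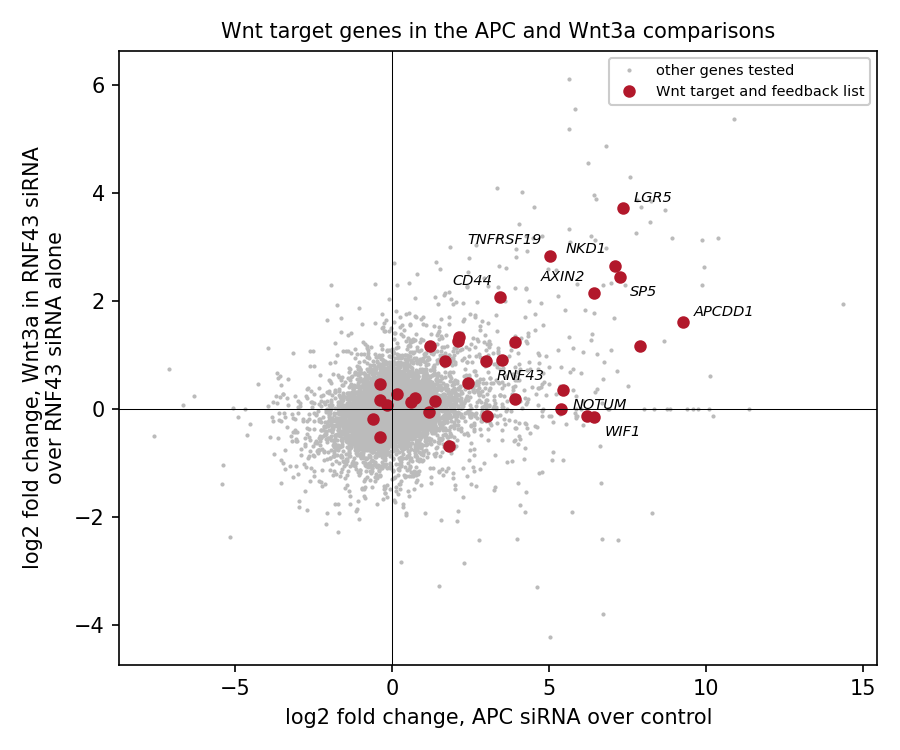
Each point is a gene tested, with its log2 fold change after APC siRNA against control on the horizontal axis and its log2 fold change with Wnt3a in RNF43 siRNA cells on the vertical axis. The 33 Wnt target and feedback genes are drawn as large red points, and AXIN2 (6.41 and 2.14), NKD1 (7.10 and 2.65), SP5 (7.24 and 2.43) and LGR5 (7.36 and 3.72) lie at the upper right, while WIF1 (6.44 and -0.14) and NOTUM (5.43 and 0.35) lie near the horizontal axis.

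The APC and Wnt3a comparisons share no library, so their changes can be compared directly. Log2 fold changes correlated at r = 0.319 (Spearman rho = 0.165) across 16295 genes, which are not independent replicates. Of the 379 genes higher after APC knockdown, 205 (54.1%) were also higher with Wnt3a in both RNF43 siRNAs, against 26.6% of all genes tested. As a set they had a median log2 fold change of 0.28 with Wnt3a (camera p = 9.15e-34, p = 0.0292 with an estimated correlation, and p = 0.051 with that and the replicate block). Of the 73 lower genes, 52 (71.2%) were lower with Wnt3a in both siRNAs, against 25.4% of all genes (camera p = 5.78e-17, p = 0.0168 with an estimated correlation). With the replicate block, 6 of the 6 genes called with Wnt3a were among the 597 higher after APC knockdown, where 0.22 were expected for independent lists (Fisher's exact test, p = 2.36e-09). With DESeq2 20 of 24 were shared, with 1.16 expected (Fisher's exact test, p = 3.61e-23). In each case both comparisons came from the same fit, with a shared spread per gene. Genes of low spread are called more easily in both, so the lists are not independent and these p may be too small.

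The change after APC knockdown exceeded the Wnt3a change in 23 genes and was below it in 1, APC itself (edgeR test of the difference, 16295 genes). Time and baseline differ between these arms, so the difference does not measure pathway strength alone. The 23 included NKD1 (difference 4.45 ± 0.45), SP5 (4.81 ± 0.49), AXIN2 (4.27 ± 0.54), ZNRF3 (2.58 ± 0.34), APCDD1 (7.66 ± 0.97), CST1, the GABA synthesis gene GAD1 (4.98 ± 0.48) and the insulin receptor substrate gene IRS1 (3.50 ± 0.33), of which APCDD1, GAD1 and IRS1 were named after their values were seen. The difference for ROR1 was 1.3 ± 0.40 (edgeR adjusted p = 0.49). With the replicate block 50 genes were above and 2 below, DESeq2 called 221 and 23, and limma-voom 0 and 0. Each library left out in turn moved the 23: 0 genes were above without control replicate 1, control replicate 2, APC siRNA 2, RNF43 siRNA 3 or RNF43 siRNA 4, 4 without APC siRNA 4, 2 without siRNA 3 with Wnt3a and 1 without siRNA 4 with Wnt3a, and 0 were below in each case.

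RNF43 knockdown without Wnt3a gave no call over all genes against control either. Of the always-named genes besides the target, WNT5A had 3.08 and 4.26 CPM in the controls and 19.4 and 5.13 CPM after siRNA 3 and siRNA 4 (log2 1.74 ± 0.78, edgeR adjusted p = 0.642), ROR1 had a log2 fold change of -0.44 ± 0.29, ROR2 of -1.77 ± 1.03 and AXIN2 of 0.04 ± 0.38. The smallest p on the higher side were those of the ubiquitin-conjugating enzyme gene UBE2S (log2 1.78 ± 0.22, edgeR adjusted p = 0.382), the interferon-stimulated OAS3 (1.22 ± 0.20), the tubulin gene TUBA1B (1.45 ± 0.23), LIN7A (2.0 ± 0.34) and the pseudogene UBE2SP1 (1.89 ± 0.35), whose reads may not be separated from those of UBE2S. On the lower side, after RNF43, they were MTURN (-1.51 ± 0.20, edgeR adjusted p = 0.382), CLMN (-1.47 ± 0.23), NEB (-2.44 ± 0.42) and the Frizzled receptor gene FZD7 (-2.47 ± 0.43), which had 9.35 and 18.7 CPM in the controls and 2.65 and 2.42 CPM after siRNA.

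The edgeR test called 0 higher and 0 lower, with 1219 genes at an unadjusted p under 0.05. DESeq2 called 24 and 32, limma-voom 0 and 0, and the replicate block 0 and 0. Without control replicate 2 edgeR called 38 higher and 1 lower, and without control replicate 1 it called 1 and 8. The 38 included the mitotic genes AURKA (log2 2.42, adjusted p = 0.0357), PLK1 (2.89, 0.0376) and CCNA2 (2.39, 0.0357), which were named after their values were seen.

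In this comparison 3 lists passed with camera and none with an estimated correlation, and 0 members of any list passed over all genes tested in edgeR. DESeq2 called E2F1 (adjusted p = 0.0039), CDC6 (0.0298) and OAS3 (0.000119) higher, and ID2 (3.96e-05), ID3 (7.19e-05), SMAD6 (0.0235), FZD7 (7.35e-05) and TRPM8 (0.0039) lower. Proliferation genes were higher (adjusted p = 2.75e-13, adjusted p = 0.641 with an estimated correlation), with 2 of 28 higher adjusted over the list alone, among them the S-phase regulators E2F1 (log2 1.42 ± 0.28) and CDC6 (1.06 ± 0.24). Their median log2 difference was 1.6 against control replicate 1 and 0.13 against control replicate 2, and without control replicate 1 the list no longer passed (adjusted p = 0.337). TGF-beta and BMP targets were lower (adjusted p = 3.14e-07, adjusted p = 0.641 with an estimated correlation), and 5 of 17 fell adjusted over the list alone. The inhibitor of differentiation genes ID1 (-5.20 ± 1.38), ID2 (-3.14 ± 0.62) and ID3 (-3.56 ± 0.77) were among these, and the list's median was -0.29 against control replicate 1 and -1.99 against control replicate 2. ID1 had 68.8 and 494 CPM in the controls and 13.9 and 1.49 CPM after siRNA. Cholesterol synthesis genes were higher (adjusted p = 5.67e-10, adjusted p = 0.641 with an estimated correlation), with 0 of 24 passing adjusted over the list alone. Their median was 0.29 against control replicate 1 and 0.87 against control replicate 2, and MVK had a log2 fold change of 1.45 ± 0.41. The remaining lists had camera adjusted p from 0.109 for interferon-stimulated genes to 0.854 for markers of other cell types. Adjusted over the list alone, RNF43 in the Wnt target list, FZD7 in the receptor list and TRPM8 in the androgen list (-1.10 ± 0.20) fell and OAS3 in the interferon list rose. Without control replicate 1 the histone and nuclear RNA list was called lower (camera adjusted p = 0.0307), and without control replicate 2 the antagonist list higher (0.0213) and the androgen list lower (0.0105). Without RNF43 siRNA 3 the neuroendocrine (0.0272) and histone and nuclear RNA lists (0.00694) were lower, and without RNF43 siRNA 4 the interferon list was higher (0.000594).

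The APC and RNF43 knockdown comparisons used the same controls. Their log2 fold changes correlated at r = 0.2 (Spearman rho = 0.322) across 16295 genes, below the mean of 0.487 in 40 simulations of unchanged groups against those controls. The covariance was 0.118, against 0.133 in the simulations, a difference of -0.015, and 63.4% of genes had the same sign in both, against 66.5% in the simulations. In edgeR 0 calls were shared, as RNF43 knockdown had none. In DESeq2 3 higher and 8 lower genes were shared, with 1.16 and 0.59 expected for independent lists, and part of that excess may come from the shared controls, which are too few to split.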

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

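The fits that combine the replicate block with DESeq2, with limma-voom or with the omission of control replicate 2, and limma-voom for the difference, were chosen after the data were seen; the others were planned. None of the 379 higher and 73 lower calls after APC knockdown changed sign in any setting, and DESeq2 kept 366 and 70 of them. In the Wnt3a comparison, samples grouped by the treatment tag, which exchanges a library of each group, gave 126 higher and 277 lower genes, and WNT5A (-2.05), TLE4 (-3.06) and LYZ (-2.99) reversed; this grouping compares siRNA 4 with siRNA 3. The same grouping gave 14 higher and 20 lower genes for RNF43 knockdown. The cause of the other changes was not tested, except that fewer libraries give fewer degrees of freedom. A lone library left in a group was assumed to vary like the other groups.

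DESeq2 called 790 higher and 299 lower after APC knockdown, 24 higher with Wnt3a, 24 higher and 32 lower after RNF43 knockdown, and 221 above and 23 below for the difference. It gave RNF43 a log2 fold change of -2.64 (adjusted p = 1.77e-17), and 20 shared genes for APC and Wnt3a, and 3 higher and 8 lower for APC and RNF43. Without a filter on low counts edgeR called 1085 and 596, 83 and 13, 115 and 172, and 394 and 123 in the same order. The 4 compared libraries alone gave 230 and 23 after APC knockdown, RLE gave 1 higher with Wnt3a, and all 4 RNF43 libraries against control gave 1 lower gene. For the difference, limma-voom gave 0 and 0.

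The replicate block gave 597 and 193 after APC knockdown, 6 higher with Wnt3a, all 6 shared with APC knockdown, and 50 above and 2 below for the difference. After APC knockdown it also added calls for named genes, among them CDH2 (3.23, edgeR adjusted p = 0.0125), LYZ (2.77, 0.00853), ABCC4 (-0.95, 0.0413), SCGN (-1.3, 0.00857), STARD4 (1.28, 0.0316) and WNT2 (-1.98, 0.0418). Beyond these and the values given beside the results, it moved no count of calls by more than 1.5 times, ended no call of a named gene in the 3 comparisons and changed no call of a list with the preset correlation. In simulated data with 200 of 16295 genes changed, it made 29 false calls over 3 simulations of the Wnt3a comparison, 43 of the APC comparison and 44 of the RNF43 comparison, against 3, 4 and 2 without the block. It also recovered more true changes, 84.7%, 87.3% and 84.7% of 4-fold changes in the same order against 55.3%, 54.7% and 56%, and 15.3%, 17.3% and 22% of 2-fold changes against 0%, 2% and 1.3%. The block with DESeq2 gave 54 higher and 2 lower with Wnt3a, and with limma-voom 2 higher. The block without control replicate 2 gave 1355 and 903 after APC knockdown and 447 and 266 after RNF43 knockdown.

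Leaving out each library gave 57 to 450 higher and 1 to 404 lower after APC knockdown, 0 to 2 higher with Wnt3a, 0 to 38 higher and 0 to 8 lower after RNF43 knockdown, and 0 to 4 above and 0 below for the difference. RNF43 then ranged from -2.89 to -2.37 after its knockdown. Between 3 and 6 lists passed after APC knockdown, 2 to 5 with Wnt3a and 3 to 5 after RNF43 knockdown, and the proliferation list reversed after APC knockdown without control replicate 2 (camera adjusted p = 6.29e-07; 6.78e-14 downward to 0.533 without the other libraries). With an estimated correlation 0, 0 and 0 lists passed, and with fry 1, 0 and 0. The set of genes raised by APC knockdown no longer passed in the Wnt3a comparison with fry. Of the values of named genes in other settings, 873 kept direction and call after APC knockdown, 103 lost a call and 90 gained one. With so few 2-fold changes recovered in simulated data, a missing call does not show that a gene did not change.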

Other observations

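The tests of overlapping genes, culture state, knockdown depth and sample titles were chosen after the results were seen. The guide strand test was chosen once the leading sequence was known, and the genes named in this part were chosen after their values were seen.

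The RNF43 libraries differed by siRNA number, with and without Wnt3a. In the model over all 8 libraries, with the RNF43 libraries grouped by siRNA, 126 genes were lower with siRNA 3 and 277 lower with siRNA 4 (edgeR, adjusted p under 0.05). The deubiquitinase gene USP8 had 91.1 and 84.5 CPM in the controls, 59.4 and 64.3 CPM with siRNA 3 and 9.29 and 8.05 CPM with siRNA 4 (log2 -2.84 for siRNA 4 against siRNA 3, edgeR adjusted p = 0.00174). The N-cadherin gene CDH2 had 5.85 and 6.86 CPM with siRNA 3 against 0.149 and 0.27 CPM with siRNA 4. The death ligand gene TNFSF10 had 30.8 and 25.7 against 6.21 and 6.13 CPM, and the phospholipase gene PLA2G2A 172 and 145 against 10.96 and 18.7 CPM. The Notch-regulated NRARP was lower with siRNA 3, at 14.7 and 13.8 against 48.4 and 59.5 CPM. The noncanonical ligand gene WNT5A stood at 19.4 and 21.3 CPM with siRNA 3 and at 5.13 and 4.69 CPM with siRNA 4 (edgeR adjusted p = 0.0173).

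The control libraries also differed from each other. Control replicate 2 lay further than control replicate 1 from each library of the other groups. Its SD of the log2 ratio over genes was 0.799 to 1.088, against 0.637 to 1.004 for replicate 1. Control replicate 1 had 707 CPM of SLC45A3, 563 of the neuropeptide gene NPY and 791 of FOLH1, and control replicate 2 had 46.8, 36.2 and 103. Control replicate 2 had more of the mitotic gene TOP2A (863 against 166 CPM), the chromatin gene HMGB2 (835 against 82.4), ID1 (494 against 68.8) and the metallothionein gene MT1X (146 against 7.79). With 1 library on each side these are descriptions of those libraries.

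The spread between the controls, an SD of 0.834 of the log2 ratio over genes, exceeded that of the pairs in the other groups, of 0.424 to 0.755. Different counting of overlapping genes is argued against as the whole cause, as the SD ratio to the APC pair was still 2.23 over 6246 genes without an overlapping neighbour. A smooth fit on GC content and length gave an R2 of 0.081, which argues against those biases. A different growth and androgen-response state of the cultures may account for part of it. In replicate 2, 27 of 28 proliferation genes were higher (median log2 1.67). Androgen-induced genes went both ways, with 12 of 31 higher and a median of -0.33. Cholesterol synthesis genes (median -0.67) and TGF-beta and BMP targets (1.6) differed as well. With 1 library each, such a state cannot be told apart from chance or handling.

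In the 126 genes lower with siRNA 3, the separation of RNF43 libraries by siRNA may in part reflect off-target silencing through its seed. The sequence of siRNA 3 is not given in the sources used here. This does not cover the 277 genes lower with siRNA 4. For these the search below gave no sequence beyond its permutations, which does not exclude an off-target effect of siRNA 4. Libraries with the same siRNA may also share a culture or transfection set, which cannot be told apart from the siRNA, and the control pair differed by more (SD 0.834 of the log2 ratio, 2846 genes over 2-fold) than siRNA 3 and 4 did without Wnt3a (0.657, 1634) or with it (0.755, 2298). Of 14385 7-mers in 3' untranslated regions of 12095 genes, TTGCACA was most enriched in genes lower with siRNA 3 (statistic 7.63, against at most 4.49 in 100 permutations; in 47.8% of the searched genes called lower and 15.6% of all), the overlapping TGCACAA (5.68) and ATTGCAC (4.92) and the non-overlapping TTTTTTA (5.6) and GGTTTTT (5.17) passed that bound too, and the siRNA 4 side gave 4.53 against 4.9. Among searched genes called lower with siRNA 3, the median log2 difference of siRNA 3 from control was -0.72 in 55 genes with TTGCACA. It was -0.49 in 60 genes without it, so those were lower as well. With siRNA 4 the same medians were 0.39 and 0.5, above control. The 7-mer occurs 1 time in 6 of 8 annotated RNF43 transcripts and 0 times in the others. A guide strand matching those 6 would need this. However, 27.4% of transcripts of similar length hold it too, and an endogenous microRNA with an overlapping seed was not tested. Unequal knockdown of RNF43 mRNA is argued against, as it differed at most 1.17-fold between siRNAs at matched Wnt3a, with 1 library each. RNF43 protein was not measured in these data, so unequal loss of the protein is left open.

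Wnt targets were higher in the libraries titled Wnt3a (median log2 0.30 for siRNA 3 and 0.33 for siRNA 4), while the treatment tags name another pair. If the tags were right, the Wnt target list would be higher in the tag split, where its median was -0.20 with quartiles of -0.76 and 0.09. Its members went both ways (9 of 33 higher), and this split also parts siRNA 4 from siRNA 3. The split alone therefore cannot tell wrong titles from wrong tags. Its quartile rule replaced one on the sign of the median after the value was known, and the first rule argued against the tags. The tags put both libraries of an siRNA under the same treatment. Yet AXIN2 rose by the titles within each, from 8.03 to 30.8 CPM (siRNA 3) and 3.79 to 21.3 CPM (siRNA 4). By the titles 25 of 33 members were higher (camera adjusted p = 1.66e-27, and 0.136 with an estimated correlation). The titles were used because of the design text. No biological explanation of this pattern was tested.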
